A study of Mus musculus with 4 samples.

How the data were processed

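RNA polymerase II was measured by chromatin immunoprecipitation and sequencing in heart, kidney, liver and lung of C57BL/6 mice, with 1 list of called regions per organ. Per the labels' protocols, flash-frozen organs of 2 mice were crosslinked, chromatin was sheared in a 96-well plate, precipitated with an antibody to the C-terminal domain, made into libraries by Tn5 tagmentation and read as 50-base pairs. Whether a list pools both mice, and the sex of the mice, are not given in the sources used here.

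Reads were processed with Bowtie2 2.2.8 and HOMER 4.8 on mm10, per the submitters' processing notes. Regions were called by the authors with findPeaks in histone style, per the file headers, with windows of 500 bp joined into regions of variable length, a Poisson p threshold of 0.001, a genome size of 2 Gb, a fragment length of 78 bp and at most 1 tag considered per bp. The deposited tag counts exceed that limit in places (10870 tags per kb on the mitochondrial genome in heart), so they did not follow it there. No control library is named in the recorded command, so local bias of open chromatin or copy number was not subtracted by a control. The headers state a minimum distance of 1000 bp between regions, whereas the smallest gap in each list was 500 bp. The deposited signal of a region is a tag count scaled by the authors to 10000000 tags, per the file headers. The deposited score of a region is the caller's own score, and the deposited ratio is its clonal fold change, per the file headers. Region lengths were also deposited. How tags matching several places were treated is not given in the sources used here, so genes with close paralogs are uncertain.

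The lists rested on 9880184 tags in heart, 16589890.5 in kidney, 20058183 in liver and 13296938 in lung. The tag thresholds stated in the headers were 9, 12, 14 and 11 tags, or 9.11, 7.23, 6.98 and 8.27 per 10000000, and each list also holds regions with a lower deposited tag count, so these are not the level below which a gene has no region. Tag counts followed region length closely (Spearman's rho across regions 0.94 in heart, 0.95 in kidney, 0.98 in liver and 0.95 in lung) and the score weakly (0.38, 0.33, 0.33 and 0.36).

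Gene positions came from a table of the GRCm38.p6 assembly, the assembly behind mm10, restricted to 21887 protein-coding genes on chromosomes 1 to 19, X and Y. The table gives no strand, so the start of transcription could not be placed. The planned window of 1 kb either side of the start was replaced by 1 kb either side of each gene end, and a gene or region counted when at least 1 bp of a window was overlapped. The covered percent of a gene is the share of its annotated span, introns included, inside regions of a list. A gene was called covered at 50% or more, a measure chosen beforehand as a second choice to the gene-end count, and the text leads with it because it does not need the strand, a choice made after the data were seen. A long region also covers neighbouring genes. Regions of different organs overlapping by at least 1 bp were joined into linked regions. Regions were placed at random 100 times on their own chromosomes, and each gene list was set beside 10000 random lists of equal size matched on gene span in 10 bins. Percentages of random lists describe a library and are not p-values. The region score was used within a list only. Tag counts, which the authors scaled to the same total, rank regions within a list in the report and are set between lists for the mitochondrial genome and for a locus each on chromosomes 17 and 2.

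The 23 gene lists, with 593 distinct genes of which 45 stand in more than 1 list, the named-gene rule, the designs and most other settings were fixed before the data were examined. Of the 593 symbols, 591 matched directly, 1 through a synonym, and Ahsp did not match. The rule names, per organ, the 6 organ-restricted genes and the 5 genes with the highest region score, members of the organ's own lists with no region near an end (up to 6), and 3 members of each list by score. Some genes that the rule or the lists hold are not reported here. Rankings by tag count were added after the data were seen, and other list members given as examples were chosen after their values were seen.

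Interval and overlap code was tested on simulated queries, where 100% of 2000 covered lengths and of 2000 overlap calls equalled per-base counts. Of 200 random lists of 30 genes, 2% lay above the 95th and 5.5% below the 5th percentile, and all 50 lists with 20 of 30 members set to occupied lay above the 95th. Occupancy in these list tests was simulated independently for each gene, so they do not cover lists whose members share a region. Alternatives covered the gene-end window (500 and 2500 bp), the overlap (50% of the shorter region), subsets of regions by score, and genes without close neighbours. Added ones were subsets by tag count, a minimum of 10 tags per 10000000, both gene ends, and organ-restricted genes with 50% of the span covered. The mitochondrial chromosome was left out of gene counts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.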

Results

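Occupancy of RNA polymerase II (Pol II) was profiled by chromatin immunoprecipitation and sequencing in 4 organs of C57BL/6 mice, the heart, the kidney, the liver and the lung. The organs came from 2 mice, and their chromatin was sheared in parallel in a 96-well plate by PIXUL, an ultrasound instrument that treats many samples together. The antibody (4H8) binds the C-terminal domain of the largest Pol II subunit. The purpose was to compare Pol II binding across the organs of the same series. One list of called Pol II regions per organ was analysed, so n = 1 per organ, no value has a replicate error, and no difference between organs was tested. The lists rested on 9880184 tags in heart, 16589890.5 in kidney, 20058183 in liver and 13296938 in lung. Tag counts and scores of a region are the authors' own, and the scores are used within a list only. A gene without a region was not called in that list, which is not the same as lacking polymerase. The lowest deposited tag count of a region was 6.07 per 10000000 tags in heart, 5.42 in kidney, 5.23 in liver and 5.64 in lung. Intervals are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only.

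At least 50% of the span lay inside called regions for 16.1% of protein-coding genes in heart, 21.1% in kidney, 21.9% in liver and 15.1% in lung, and 66.9% of genes were covered to this extent in no list. By tag count, the leading heart regions on the nuclear chromosomes included those over Zbtb16, a glucocorticoid-responsive transcription factor (chromosome 9, 48642645 to 48840545 in mm10, 198 kb), Tns1, Ablim1, the cardiac calcium pump gene Atp2a2 and Ryr2. The leading kidney regions lay over Tns1, over Lrp2, which encodes the endocytic receptor megalin of the proximal tubule (chromosome 2, 69421643 to 69593102, 171 kb), and over Rbm47, Rbpms, Cgnl1 and 8 genes of the Hoxb cluster. The longest region of the 4 lists was a liver region of 338 kb over Ap3m1 and parts of Vcl and Adk (chromosome 14, 21022933 to 21360561), and the next liver regions overlapped 21 genes on chromosome 11, and then Egfr, Scp2, Zbtb16 and Cps1, the first enzyme of the urea cycle. In lung the leading region spanned the non-coding RNA genes Malat1 and Neat1 (chromosome 19, 5779912 to 5853517), followed by Zbtb16 and by Epas1, a hypoxia-inducible factor of endothelium. Malat1 and Neat1 were covered over 100% of their spans in all 4 lists.

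The lists held 81887 regions in heart, 88200 in kidney, 61956 in liver and 101051 in lung. The liver list had the fewest regions and the largest covered length, 210 Mb, against 200 Mb in kidney, 163 Mb in heart and 161 Mb in lung. Median region length was 730 bp in heart, 783 bp in kidney, 951 bp in liver and 696 bp in lung, and 411 liver regions exceeded 50 kb compared with 145 in kidney, 113 in heart and 23 in lung. Regions overlapping 1 kb either side of an end of a protein-coding gene made up 16.2% of the heart list (interval 15.9 to 16.4%), 16.7% of the kidney list (16.50 to 16.99%), 19.8% of the liver list (19.4 to 20.1%) and 15.2% of the lung list (14.98 to 15.42%). Random placement of the same regions gave means of 5.63%, 5.87%, 6.75% and 5.28% in the same order. Between 68.8% of covered bases in lung and 71.8% in heart fell inside protein-coding gene spans, where random placement gave 40.4% in liver, 40.4% in kidney, 40.5% in heart and 40.5% in lung.

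Most linked regions, formed by joining regions of different organs that overlap by at least 1 bp, belonged to a single organ. Of 152554 linked regions, 103723 (68.0%) were held by 1 organ, 25262 by 2, 11512 by 3 and 12057 (7.90%) by all 4. A linked region held by 1 organ is a single called region, whereas a shared one joins several, so 68.0% is not a share of called regions. Lung alone held 31507 of its 101051 called regions, kidney 27590 of 88200, heart 25366 of 81887 and liver 19260 of 61956. Of an organ's called regions, 40.2% (kidney with heart) to 51.3% (liver with kidney) overlapped those of another organ, taken pair by pair. Random placement gave means of 10.5 to 13.5%. By shared covered bases, kidney and liver were the closest pair (Jaccard index 0.344), heart and lung followed (0.302), and heart and liver were the farthest apart (0.247), where random placement gave means of 0.0364 to 0.0449 over the 6 pairs. Kidney and liver also had the largest covered lengths and the highest random mean, and covered length was not equalised between the lists. Across protein-coding genes, the covered percentage of the gene span correlated most between heart and lung (Spearman's rho 0.80), followed by kidney and lung (0.79) and kidney and liver (0.77). It correlated least between heart and liver (0.67), and genes are not independent replicates. The count held by all 4 organs was 4253 when the 50% of each list with the top scores was used, and the order of the organs by regions held alone differed between selections of regions. With equal numbers of top-scoring regions liver alone held 24046, heart 21433, kidney 19976 and lung 19055, and with equal numbers by tag count liver alone also held the most (23195) and lung the fewest (15427). In both, the other lists were cut to the size of the liver list, so the liver count could not fall.

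**Figure D1:**
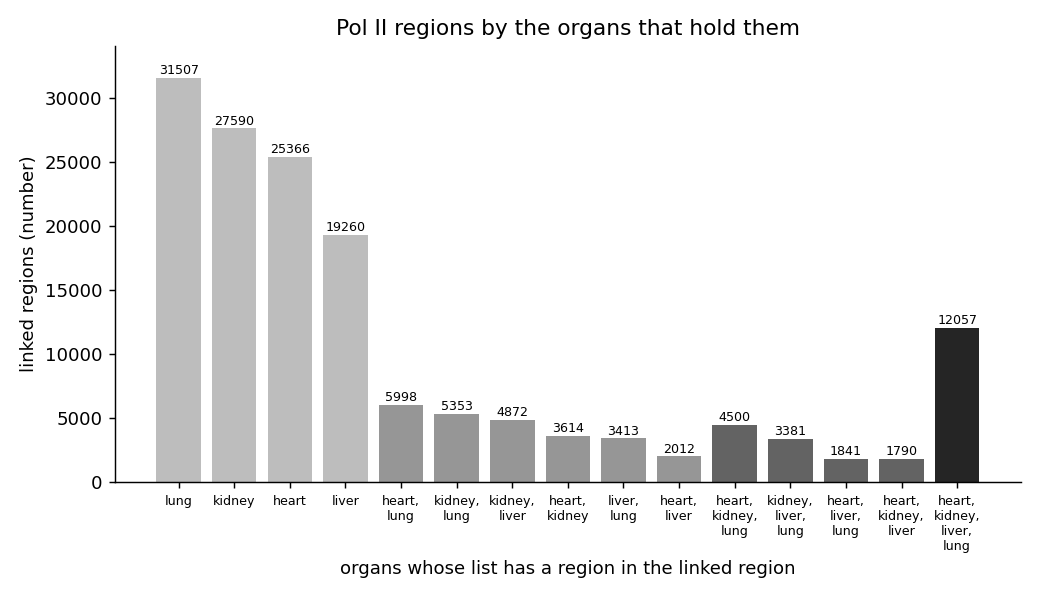
Number of linked regions (vertical axis) for each combination of organs whose list holds a region in them (horizontal axis); grey shades mark combinations of 1, 2, 3 and 4 organs. In the full lists lung alone held the most (31507) and all 4 organs held 12057, whereas with equal numbers of top-scoring regions liver alone held the most (24046) and lung alone the fewest (19055) of the 4. For equal numbers the other lists were cut to the size of the liver list.

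A region near a gene end was found in each of the 4 lists for 29 or 30 of 30 housekeeping genes and for 25 or 26 of 26 immediate early and stress genes. Of 21887 protein-coding genes, 11248 had a region within 1 kb of either end in heart, 12434 in kidney, 11657 in liver and 11978 in lung. The gene table used gives no strand, so these counts are upper bounds for genes with a region at the start of transcription. Requiring a region near both ends gave 5632, 6931, 6385 and 6192 genes. A region near an end was present for 8684 genes (39.7%) in all 4 lists and for 7031 (32.1%) in none. Actb and Gapdh were covered over 100% of their spans in all 4 lists. Genes with the highest region score included Tacc2, Tuba1b, Slc43a3 and Cmss1 in heart, Tacc2, Chl1, Atp6v0c and Kctd16 in kidney, Alb, Kng1, Acat3 and Acat2 in liver, and Apool, H2ac18, Actg1 and Dcaf6 in lung. The kidney regions of Chl1 and Kctd16 were single 500 bp stretches covering 0.22% and 0.17% of those genes. In lung 1.02% of Apool and 6.94% of Dcaf6 were covered, against 100% of H2ac18 and 76.7% of Actg1.

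The heart list covered most of the cardiomyocyte genes. Of 40 cardiomyocyte genes, 35 had at least 50% of their span inside heart regions, against 4 in kidney, 5 in liver and 2 in lung. By regions near a gene end the counts were 39 in heart, 15 in kidney, 12 in liver and 14 in lung. All 10000 random lists of matched gene span had fewer than 35 covered genes in heart, with a median of 6. Myh6 and Myh7, the alpha and beta cardiac myosin heavy chains, lay inside one 87.0 kb heart region (chromosome 14, 54931564 to 55018593) that also spanned Il25 and Cmtm5 and reached into Ngdn. The titin gene Ttn was covered over 97.3% of 279 kb and Ryr2, the cardiac calcium release channel, over 96.3% of 554 kb, with no kidney, liver or lung region in either gene. The transcription factor genes Nkx2-5 and Hand2 were covered over 100%, Gata4 over 96.8% and Tbx20 over 60.4%, and of these Gata4 (81.3%) and Nkx2-5 (50.8%) also passed 50% in liver. By score the leading list members were Ryr2, Corin and Myom1. The 5 members under 50% were Tbx5 (21.2%, and no region near an end), Myl4 (7.15%), Xirp2 (5.13%), Myl7 (0%) and Nppa (0%). Heart-restricted genes, which had a heart region near an end and no region in the gene or within 1 kb in the other lists, numbered 251. Those with the highest region score were Ryr2, Olfr1396, Usp13, Trim54, Ucn and Ttn, of which Trim54 and Ucn were overlapped by one region, as were Mpv17 and Gtf3c2. Ordered by tag count instead, the first were Ryr2, Il25, Ttn, Jph2, Timp4, Des, Speg and Rbm24. Il25 lay in the region of Myh6 and Myh7, Des and Speg were overlapped by one region, and the region of Timp4 also overlapped Syn2. Heart-restricted genes numbered 383 when regions under 10 tags per 10000000 were left out, and 52 when at least 50% of the span had to be covered.

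The kidney list covered most of the proximal tubule genes. Of 32 proximal tubule genes, 29 had at least 50% of their span covered in kidney, against 9 in liver, 4 in lung and 2 in heart, and no random list reached 29 (median 7). Regions near a gene end were found for 31 in kidney, 17 in liver, 10 in lung and 7 in heart. Slc34a1, the sodium-phosphate cotransporter, the organic anion transporter gene Slc22a6, Slc5a12, Slc6a19 and Lrp2 were covered over 100%. Slc6a19, Slc22a12, a urate transporter gene, and Gatm led the list by score. The 3 members under 50% were Cubn (40.5%), Slc7a13 (20.1%) and Slc22a30 (1.43%, and no region near an end). The proximal tubule genes shared with liver above 50% were Slc27a2, Slc17a3, Acsm1, Keg1, Cyp2j5, Fbp1, Pck1, Hnf4a and Ttc36. Of 36 genes of the loop, distal tubule and collecting duct, 22 were covered in kidney, against 4 in lung, 3 in heart and 2 in liver (median of random lists 8), and regions near a gene end were found for 30, 16, 8 and 8 in the same order. By score the leading members were Kcnj10 (45.6% covered), Slc12a1 (54.4%) and Tfap2b (57.3%). Umod, which encodes uromodulin of the thick ascending limb (chromosome 7, 119462708 to 119479262), was covered over 96.3%, and Cldn8, Cdh16 and the transcription factor gene Pax8 over 100%. The intercalated cell genes Slc26a4, Slc4a1, Atp6v0d2 and Atp6v1g3 were covered over 1.75%, 3.04%, 7.71% and 11.3%, and Tmem213, of the same list, over 100%. Podocyte and juxtaglomerular genes did not stand out in kidney, where 2 of 12 were covered, among them Tcf21, against 5 in heart and 3 each in liver and lung. Regions near a gene end were found for 8 in kidney, 9 in heart, 7 in lung and 6 in liver. By score the leading members in kidney were the renin gene Ren1 (11.8% covered), Tcf21 (65.2%) and Ptpro (1.37%). In liver these were at 83.1%, 0% and 0.132%, so Ren1 was among the members covered there. The kidney count of covered members exceeded 20.2% of random lists, and the slit diaphragm gene Nphs1 had no kidney region in its span. Aqp6, Atp6v0d2, Cldn16 and Cdkn1c were further list members with no kidney region near an end. Kidney-restricted genes numbered 301, led by score by the neutral amino acid transporter genes Slc6a18 and Slc6a19, which share one 42.4 kb region, and by Fam110c, Ceacam2, Akr1c21 and Vstm5. By tag count the first were Pax8, Ano3 and Slc5a12, with Ano3 covered over 5.78% by the end of a region that spans Slc5a12. Kidney-restricted genes numbered 486 in the 50% of each list with the top scores and 62 when at least 50% of the span had to be covered.

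The liver list covered nearly the whole set of hepatocyte genes. Of 58 hepatocyte genes, 56 had at least 50% of their span covered in liver, against 9 in kidney, 2 in heart and 2 in lung, and all 58 had a liver region near an end (kidney 30, lung 21, heart 12). No random list reached 56 (median 15). By score the leading members were Alb, Kng1 and the hepcidin gene Hamp. Alb, the albumin gene (chromosome 5, 90460870 to 90476602), was covered over 95.9%, and the liver region that reached it began at 90401009 on the same chromosome. The fibrinogen genes Fga, Fgb and Fgg lay in a single 58.0 kb region that reached into Plrg1, and Apoa1, Apoc3, Apoa4, Apoa5 and Zpr1 lay in a 151 kb region that reached into Sik3 and Bud13. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, Cyp2e1, Tat and Arg1 were covered over 100%. The 2 hepatocyte genes under 50% were Otc (34.4%) and C9 (19.5%). The hepatocyte genes above 50% in kidney included Apoa2, Fgg, Ass1, Pck1, G6pc, Hpd, Nr1h4 and Hnf4a. Bile acid and xenobiotic genes were covered in liver for 23 of 25 members (kidney 5, lung 3, heart 2), and urea cycle and amino acid breakdown genes for 22 of 25 (kidney 11, heart 3, lung 1). All 25 members of each list had a liver region near an end, against 15 in kidney, 10 in lung and 7 in heart for the former and 16, 16 and 11 for the latter. By score, Sult2a8, Ugt2b1 and Slc27a5 led the former list and Aass, Otc and Sds the latter. Liver-restricted genes numbered 312, led by score by Sult2a8, Smok3a, Abcb4, Rbm12b1, F11 and Mup22, of which Smok3a was covered over 3.47% and Mup22 over 16.9%. Cps1 led by tag count, followed by Apoa4 and Onecut1. Mup22, Sult2a8 and the Serpina1 genes have close paralogs, and how reads matching several copies were placed is not given in the sources used here. Liver-restricted genes numbered 485 to 503 under 3 of the selections of regions and 135 when at least 50% of the span had to be covered.

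The lung list covered 25 of the 36 lung epithelial genes over at least 50% of their span. The counts were 10 in liver, 8 in kidney and 3 in heart, and no random list reached 25 in lung (median 7). Regions near a gene end were found for 33 in lung, 22 in liver, 19 in kidney and 12 in heart. By score the leading members were Hopx (93.9% covered), Aldh1a1 (34.9%) and Rtkn2 (54.98%). In liver these were covered over 100%, 58.5% and 9.28%, and Hopx was also at 82.4% in heart. The surfactant genes Sftpa1, Sftpb and Sftpc were covered over 100% and Sftpd over 86.0%. Nkx2-1, the lung and thyroid transcription factor gene, the club cell gene Scgb1a1, Scgb3a2 and the water channel gene Aqp5 were covered over 100%. The 11 members under 50% included Scgb3a1 (0%), Lamp3 (10.6%) and Lpcat1 (40.8%). In liver 74.7% of Sftpc was also covered, in part by a region that runs through the neighbouring gene Bmp1 (chromosome 14, 70482485 to 70522263). Over both lung lists, the genes with no lung region near an end were Pdpn, Egfl6, Dynlrb2, Ednrb, Fgf10 and Fhl1. Of 20 genes of lung mesenchyme and lung endothelium, 9 were covered in lung, among them Foxf1, Tmem100 and Tbx2 over 100%, against 7 in kidney, 5 in heart and 4 in liver. That lung count exceeded 99.6% of random lists (median 4). Regions near a gene end were found for 17 in lung, 13 in kidney, 12 in heart and 5 in liver, and Gpx3, Hpgd and Prx led by score in lung. Lung-restricted genes numbered 280, led by score by Grin3a, Rasgef1a, Chil3, Fam167a, Hmgcll1 and Tspan11. The covered percentages of these 6 ran from 1.49% (Grin3a) to 45.3% (Rasgef1a). By tag count the first included Il18r1, Cyp2b19, Cxcl15, Aqp5 and Krt19. The region of Il18r1 also overlapped Il1rl1, and most of the region at Cyp2b19 lay beyond that gene, which was covered over 13.7%. Lung-restricted genes numbered 15 when at least 50% of the span had to be covered.

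**Figure D2:**
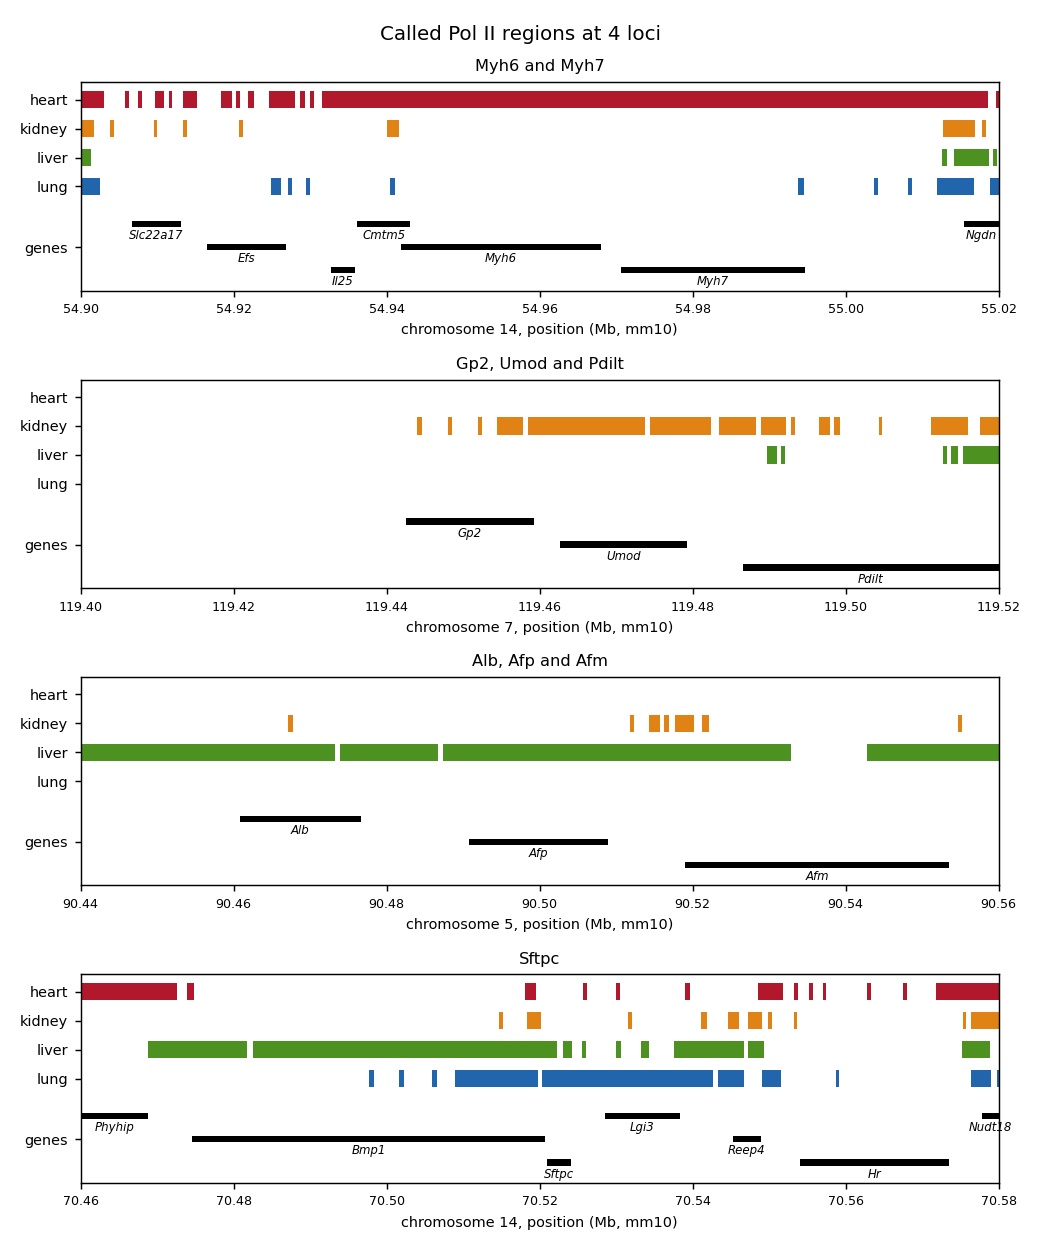
Called Pol II regions (coloured bars, 1 row per organ) and protein-coding genes (black bars) at 4 loci, with position in Mb of mm10 on the horizontal axis; each row shows 1 region list and bar height has no meaning. Heart regions span Myh6 and Myh7, kidney regions cover 96.3% of Umod, liver regions cover 95.9% of Alb, and Sftpc is covered over 100% in lung and 74.7% in liver.

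Genes of other cell types were covered to different extents. Of 30 endothelial genes, 21 were covered in heart and 16 in lung, against 6 in kidney and 6 in liver, where random lists had medians of 5, 4, 6 and 6. Cldn5, a tight junction gene of endothelium, and Sox18 were covered over 100% in heart and in lung, Kdr over 100% in heart and 65.4% in lung, and Pecam1 over 95.7% in both. By score Pecam1, Flt1 and Calcrl led in heart. Regions near a gene end were found for 29 in heart, 28 in lung, 21 in kidney and 18 in liver. Of 37 leukocyte genes, 9 were covered in lung, 2 in heart, 1 in kidney and 1 in liver, and the lung count exceeded 77.1% of random lists. By regions near a gene end the counts were 17 in lung, 13 in kidney, 9 in heart and 8 in liver, and the lung count, under the random median of 20, exceeded 11.02% of random lists. By score Chil3, Lck and Spi1 led in lung. The members covered in lung were Cd74, H2-Aa, H2-Ab1, H2-Eb1, Cd79b, Coro1a, Lyz2, Fcer1g and Spi1. For fibroblast and smooth muscle genes, 21 of 24 had a heart region near an end, above 99.9% of random lists, but 3 were covered over 50% of the span (Sparc, Mgp and Timp3). Lung had 14, kidney 10 and liver 8 with a region near an end, and by score Col3a1, Col6a1 and Timp3 led in heart. The haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt had no region in their spans in any list, and Klf1 was the 1 erythroid gene of 12 covered in heart, kidney and liver, with none in lung. Each list had 3 erythroid genes with a region near an end, and Tal1 and Klf1 led by score in heart. Skeletal muscle genes were covered for 1 or 2 of 17 members per list, with Casq1, Mylpf and Myog leading by score in heart, and 6 had a heart region near an end. Of 24 neuronal and glial genes, 1 or 2 were covered per list, and of 24 genes of testis, pancreas and retina also 1 or 2, among them Gnat1 in all 4 lists. The heart region over Gnat1, of 20.5 kb, also overlapped Slc38a3 and Sema3f, so the heart value is not specific to Gnat1. Regions near a gene end were found for 4 to 8 of the neuronal and glial genes and for 3 or 4 of the genes of testis, pancreas and retina. By score the leading members were Tbr1, Mbp and Camk2a in lung for the former and Sag, Gnat1 and Pde6b in heart for the latter.

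Along the gene span, genes of oxidative metabolism were covered more often in heart, kidney and liver than in lung, while the counts with a region near an end were closer. For fatty acid oxidation, 25 of 30 genes were covered in liver, 18 in kidney, 17 in heart and 4 in lung, and 28, 30, 29 and 26 had a region near an end. Cpt1b, the muscle carnitine palmitoyltransferase gene, was covered over 100% in heart, 55.7% in liver, 5.29% in kidney and 0% in lung, and Pdk4 over 100% in heart, 96.0% in liver, 83.3% in kidney and 1.99% in lung. The leading members by score in kidney included Acadl and Acsl1. For the respiratory chain, 25 of 32 genes were covered in kidney, 23 in liver, 22 in heart and 9 in lung, although 30 or 31 had a region near an end in each list. Cycs, Uqcrc2 and Ndufv1 led by score in heart. For glycolysis, 12 of 22 were covered in heart, kidney and liver and 6 in lung, and 20, 18, 17 and 17 had a region near an end. Pklr was covered in kidney and liver, and Hk2, Pfkm and Pkm were at 75.5%, 75.4% and 97.0% in heart. The leading members by score in heart included Eno2 and Gpi1, with 6.48% and 30.9% covered. Lung also had the lowest share of tags in regions of the 4 libraries (32.1%, against 44.1% in kidney, 46.3% in heart and 55.1% in liver).

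Most immediate early and stress genes, and 9 to 11 of the clock genes, were covered in each of the 4 lists. Of 26 immediate early and stress genes, 22 were covered in heart, 20 in kidney, 20 in lung and 19 in liver, with a median covered span of 100% in each and random medians of 7 or 8 genes. Jun, Junb, Jund, Ier2, Dusp1 and Zfp36 were covered over 100% in all 4, and Gadd45b, Hspa1a and Hspa1b led by score in heart. Gadd45b was also at 100% in all 4, but Hspa1a and Hspa1b did not count as covered in any list. Hspa1a was at 32.5% in heart, 30.5% in kidney, 14.4% in liver and 0% in lung. Hspa1b was at 13.6%, 38.8%, 35.5% and 27.6% in the same order. Of 19 circadian clock genes, 11 were covered in kidney, 10 in liver, 9 in heart and 9 in lung, and 16 to 18 had a region near an end. Per1, Nr1d1, Dbp and Bhlhe40 were at 100% in all 4, whereas Arntl was between 20.01% and 28.36% and Clock between 2.51% and 13.1%. Arntl, Tef and Rora led by score in kidney. Of 30 housekeeping genes, 22 were covered in heart, 23 in kidney, 24 in liver and 21 in lung, and 29 or 30 had a region near an end. The leading members by score in heart included Rpl4 and Ncl.

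Transcription factor genes of organ identity were covered to different extents in the 4 lists. Of 28 such genes, 15 were covered in kidney, 12 in liver, 9 in lung and 6 in heart, and 19, 15, 15 and 14 had a region near an end. The list was not split by organ, so these counts do not show how many of an organ's own factors were covered. Foxa2 was covered over 100% in liver and lung, Foxf1 over 100% in lung and 13.3% in heart, Emx2 over 100% in kidney and 7.50% in heart, and Prox1 over 100% in liver and 37.3% in heart. Cebpa was covered over 100% in kidney, liver and lung and 18.97% in heart. By score Pax2, Hnf4a and Cebpa led in kidney. The kidney count of covered genes exceeded 99.9% of random lists, the liver count 96.7%, the lung count 92.9% and the heart count 50.0%. The counts by gene end exceeded 74.4%, 31.6%, 24.1% and 23.9% of random lists in the same order.

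**Figure D3:**
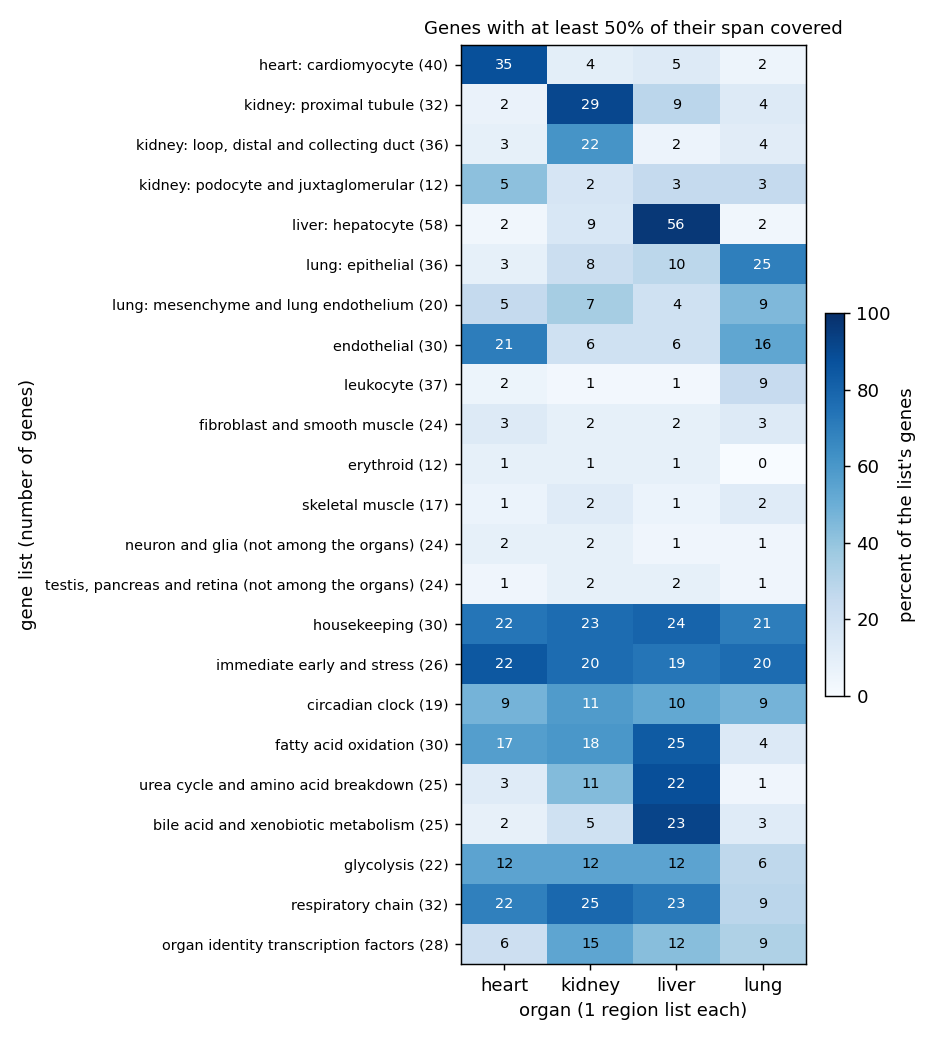
Percent of each gene list's members (colour, 0 to 100%) with at least 50% of the gene span inside called regions, by organ (columns, 1 list each); the number in a cell is the count of such genes and the number in parentheses the list's size. Cardiomyocyte genes reach 35 of 40 in heart, proximal tubule genes 29 of 32 in kidney, hepatocyte genes 56 of 58 in liver and lung epithelial genes 25 of 36 in lung.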

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

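Both tests of the mitochondrial tags were chosen after the result was seen. Called regions also lay outside the nuclear protein-coding genes of the report, and any called region lies above what a count of 0 allows (3.04 tags per 10000000 in heart, 1.81 in kidney, 1.496 in liver and 2.26 in lung) by construction. On the mitochondrial genome, heart had 147345 tags per 10000000 over 13.6 kb of regions, liver 44439.3 over 12.2 kb, kidney 13416.6 over 12.8 kb and lung 12091.2 over 12.8 kb. These were 1.47%, 0.444%, 0.134% and 0.121% of the tags, or means of 10870, 3645, 1052 and 945 tags per kb.

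The heart value was 3.32 times that of liver, the next organ. The values, scaled to equal totals, did not follow library depth in either direction, since heart, the shallowest library, had the highest, liver, the deepest, the next, and lung, between them, the lowest. An organ difference in mitochondrial DNA carried through the assay may account for the order, but the ratio of 3.32 is the pattern itself and does not test it. It cannot be told apart from any other difference between single libraries, because each organ had 1 library and no input library was analysed here. The 4H8 antibody is directed against nuclear polymerase, and no test here addressed binding in mitochondria.

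A locus on chromosome 17 (39843116 to 39848944 in heart), overlapping the ribosomal RNA pseudogene Rn18s-rs5 and the non-coding gene AY036118, had 2078.9 tags per 10000000 in heart, 1447.5 in liver, 1116.3 in kidney and 966.4 in lung. A locus on chromosome 2 with no annotated gene (98666274 to 98667465 in heart) had 4265.1 tags per 10000000 in heart, 2760.4 in lung, 1573.7 in liver and 1504.8 in kidney, over 1.19 kb, 1.18 kb, 1.17 kb and 1.12 kb. No explanation was tested for these loci.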

How the results depend on the processing

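Subsets by tag count, the minimum of 10 tags per 10000000, both gene ends and the coverage requirement for organ-restricted genes were chosen after the data were seen. Of 146 counts recomputed under an alternative, 121 stayed within 1.5 times the reported count. Some of these had little or no room to move. Liver genes with a region near an end stayed at 11657 under equal numbers of regions, which leave the liver list whole. Keeping only chromosomes 1 to 19, X and Y took the heart regions from 81887 to 81885. With equal numbers of top-scoring regions, lung alone held 19055 linked regions and liver had 485 restricted genes. With the top-scoring 50% of each list, all 4 organs held 4253 linked regions, heart alone 16377 and lung alone 20553, and restricted genes numbered 486 in kidney and 497 in liver. With equal numbers of regions by tag count, kidney alone held 17673, lung alone 15427, and liver had 503 restricted genes. At 10 tags per 10000000 or more, kidney alone held 17526, liver alone 11225 and lung alone 18283, and heart had 383 restricted genes. A region near both ends was found for 5632 genes in heart, 6931 in kidney, 6385 in liver and 6192 in lung, and for 4 podocyte genes in kidney. With at least 50% of the span covered, the counts were 2 podocyte genes in kidney, 9 lung mesenchyme and endothelium genes in lung, and 52 restricted genes in heart, 62 in kidney, 135 in liver and 15 in lung. Counts of genes under a stricter criterion on the same regions are lower by construction. With equal numbers of regions each list was cut to 61956, the size of the liver list, so liver counts held alone or restricted could not fall. The order of the organs by regions held alone turned there, with liver alone holding the most (24046 by score, 23195 by tag count) and lung the fewest. For the other counts the cause was not tested. Kidney and liver stayed the pair with the highest Jaccard index under the 4 subsets (0.210 to 0.346), and heart and liver the lowest under 3 of them, the exception being equal numbers of top-scoring regions. None of these subsets equalised covered length. Regions at gene ends ranged from 12.2 to 17.6% with 500 bp windows and from 22.8 to 26.1% with 2500 bp windows. No paired analysis was possible because each organ had 1 list. The lowest tag count of a called region was highest in heart (6.07 per 10000000), the shallowest library, and lowest in liver (5.23), the deepest. No list was recomputed at another depth, so an effect of depth on the weakest regions was not tested.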

Other observations

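The lists of sex-biased and atrial genes were written after some members had been seen, and the test on short gene spans, and Cux2 in the test on paralogs, rest on values already seen. Hox genes, which set position along the body axis, differed between the lists and were singled out after their values were seen. Of 39 Hox genes, 32 had at least 50% of their span covered in kidney, 8 in lung, 2 in heart and 0 in liver, and 37, 21, 22 and 6 had a region near an end. In kidney all 11 Hoxa genes, 8 of 10 Hoxb, 6 of 9 Hoxc and 7 of 9 Hoxd genes were covered, and one 109 kb region (chromosome 11, 96249327 to 96358660) spanned Hoxb2 to Hoxb9. In lung the covered genes included Hoxa2, Hoxa3, Hoxa4, Hoxa5, Hoxa7, Hoxa9 and Hoxb5, and in heart Hoxa2 and Hoxa7.

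The liver list covered genes of both sex-biased liver programmes. Of 18 female-biased genes 8 were covered, among them Acot3 (92.5%) and Cyp2b9 (90.0%), and of 16 male-biased genes 11, among them Slco1a1, Cyp2d9 and Elovl3 (100%). Tags of female and male animals in one list may give this, but in genes not looked at before the female-biased median was 12.0% over 8 genes and the male-biased median 76.2% over 8, which decides neither way. Female-biased genes with no gene of the same stem within 1 Mb had a median of 5.84% over 6 genes (A1bg, Hao2, Cyp17a1, Prom1, Abcd2 and Cux2), so reads shared between paralogs remain a candidate explanation for the coverage of Cyp2b and Acot genes. The genes went both ways, since Cyp17a1 was at 100%, while Sult2a1 (1.90%), Cyp3a41a (2.48%), Slc22a28 (2.33%) and Slc22a27 (2.73%), with 7 same-stem genes each nearby, were little covered, and the explanation stays open. Xist was covered over 18.4% in liver, 12.0% in kidney and 0% in heart and lung. Of the Y-linked genes, Ddx3y was covered over 5.70% in liver, and Kdm5d (1.38%), Uty (0.514%) and Eif2s3y (0.329%) were covered in heart, with Uty at 0.311% in kidney and in liver and none in lung.

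Several genes of the atrium were little covered in the heart list, with Nppa, Myl7, Sln and Bmp10 at 0% and Myl4 at 7.15%. Of these, Nppa, Myl7 and Myl4 had a heart region within 1 kb of an end, and Sln and Bmp10 had none. The ventricular genes Myl2, Myl3 and Myh7 were at 100% and Irx4 at 95.7%. The heart region over Myh7 also spans Myh6, Il25 and Cmtm5, so its value is not specific to Myh7. Of the ventricular genes not looked at before, Lbh was at 100% and Hey2 at 6.35%, with no heart region near an end. The 3 other cardiomyocyte genes of at most 2500 bp (Nppb, Tcap and Cox6a2) had a median of 100%, so the calling did not miss those short spans. These are 3 genes whose values had been seen, so they do not decide whether short spans were missed for Nppa and Myl7. Mostly ventricular tissue may account for the pattern, but 6 atrial genes not looked at before had a median of 36.2%. Kcna5 (100%), Kcnk3 (97.3%) and Nr2f2 (72.3%) were covered, and Cacna2d2, Dhrs9 and Gja5 were at 0%. The median lies midway between Nr2f2 and the genes at 0%. Nr2f2 was also covered in kidney (100%), liver (97.5%) and lung (95.7%), so its heart value is not particular to heart. Kcna5 was at 0% in the other lists, and Kcnk3 at 19.9% in liver, 2.70% in lung and 0% in kidney. The explanation of mostly ventricular tissue stays open.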
